A study of Rattus norvegicus with 12 samples.

How the data were processed

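Total RNA from thalamus and rostral ventral medulla (RVM) of rats was sequenced in 12 libraries, 3 for each of 4 groups: thalamus saline, thalamus CFA, RVM saline and RVM CFA. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq kit, which is not stated to be stranded. The authors deposited a single table of FPKM values (fragments scaled for gene length and library size) with gene length, coordinates and biotype for 34525 genes listed by Ensembl rat identifiers, per the file headers. Of these, 22250 were protein coding, 1642 had no name and 10358 were at 0 in all libraries. The aligner, counting tool, genome build and annotation release are not given in the sources used here, so coordinates are printed as the table lists them.

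The depth was recovered from the values. FPKM multiplied by gene length was, in each library, a whole multiple of a single step for 100% of values within a tolerance of 0.01, so each step was taken as 1 read. This gave 19.1, 16.7 and 16.73 M reads in thalamus saline, 16.27, 15.32 and 14.98 in thalamus CFA, 17.15, 14.94 and 17.47 in RVM saline and 18.45, 19.24 and 16.84 in RVM CFA. The library total that the authors divided by differed from the recovered total by a factor of 0.9335 to 1.168, which was 1.109 to 1.168 in thalamus CFA and 0.9609 to 1.0415 in thalamus saline, so the deposited FPKM carried a further scaling between libraries whose method is not given in the sources used here. A gene listed at 0 holds 0 recovered reads, and the upper limit of its expected count was taken as 3 reads, or 0.151 to 0.215 CPM. Replicates differed by more than sampling noise in all 12 pairs, with a chi-square per degree of freedom of 7.83 to 66.27, and no library repeated another.

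Groups were taken from the tissue and treatment labels. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an empirical Bayes trend, for genes with a mean of at least 1 FPKM over the libraries compared. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. CFA and saline were compared within each region, with 6 libraries per fit and 4 residual degrees of freedom. The difference of the CFA effects was the interaction of region and treatment over 12 libraries, for genes with a mean of at least 1 FPKM in each region, and the saline libraries of the regions were compared with each other. Log2 changes are on the log2(FPKM + 1) scale and understate the change of low genes.

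Before the data were examined, 36 gene lists were fixed. They covered immune and glial genes, markers of neurons and of neighbouring tissues, neurotransmission, respiration, translation, stress responses and the clock. Of their 618 symbols 604 matched the table, 9 through synonyms and 13 mitochondrial names by their form in the table, and 14 did not. Lists with at least 5 tested members were tested against the other genes with limma's camera, with a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts of members adjusted over the list alone used the members' p-values only.

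Named genes followed a rule fixed before the data were examined. In each CFA comparison these were the 12 largest rises and 12 largest falls among genes that passed, filled to 12 by the smallest unadjusted p where fewer passed. In each list described, up to 4 members that passed over all genes or over the list alone were eligible, and otherwise the 3 with the smallest p. The 6 genes per direction with the smallest p were taken for the interaction, and for the region comparison the 5 largest differences per direction and up to 4 members per list. Fos, Oprm1, Penk, Pdyn, Tph2, Gfap, Aif1, Bdnf, Tac1 and Calca were given wherever tested. Symbols that are bare identifiers were passed over, including accession-like names, noncoding family codes and a dash, and 3 genes that the rule took are not reported here.

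Alternatives were another pseudocount (0.1), no filter and a filter at 5 FPKM, rescaling each library to the same total, median-of-ratios scaling, quantile normalization, robust empirical Bayes, library quality weights, the replicate number as a block, all 12 libraries in a single model, and leaving out each library in turn. The design assumed that tests for counts would be run if whole reads could be recovered. Whole reads were recovered, but these tests were not run because the deposited unit is FPKM, which departs from the design. In their place limma-voom on the recovered reads was used. It was chosen after the data were examined, as were the fits without thalamus CFA libraries 1 and 2 and without thalamus saline 1 and CFA 1. Single values were compared by exact two-sided permutation tests.

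The fits were tested on simulated data drawn from the libraries' own means and depths. Every gene had the same preset spread between replicates, genes were drawn independently, and the lowest genes were not changed. The real libraries did not set that spread, and RVM CFA library 2 stood far from the others. The shares below therefore hold for the simulated setting and not for the real libraries. In thalamus, with 14722 genes, 25.4% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 12.1% of calls were false. In RVM, with 14289 genes, 17.9%, 74.6% and 100% were recovered, with 7.9% false. For the interaction, with 13738 genes, 3%, 40.3% and 100% were recovered, with 13.6% false, and for the regions, with 14396 genes, 26.9%, 92.5% and 100%, with 8.2% false. By voom in thalamus the shares were 41.8%, 92.5% and 100%, with 3.7% false. In the simulated thalamus comparison a list of 21 genes shifted 1.5-fold was the only call among 33 lists. As the genes were drawn independently, this does not test camera where genes of a list move together. Tables were prepared with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and statmod 1.5.0 was used for the random block.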

Results

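Gene expression was measured by RNA sequencing in 12 rat brain samples of a series on chronic orofacial pain. The samples came from 2 regions, the thalamus, the forebrain relay of sensory signals to the cortex, and the rostral ventral medulla (RVM), a brainstem region that sends descending projections which facilitate or inhibit spinal and trigeminal pain signals. In each region 3 samples were labelled as saline (0.9% sodium chloride) and 3 as CFA. In rodent pain studies these letters usually stand for complete Freund's adjuvant, an oil emulsion that raises a lasting local inflammation. The labels give the letters alone, with no dose, site or time. They do not say whether the samples came from separate animals, so p-values measure only the spread between these samples. Each library held 14944794 to 19243108 reads assigned to genes (14.94 to 19.24 M), a depth at which 3 reads, taken as the upper limit of the expected reads of a gene listed at 0, correspond to 0.151 to 0.215 CPM (counts scaled by library size). Those limits and the counts behind them cover counting error only. Part of the extraction text speaks of retinas. The 11 photoreceptor and retina genes measured reached at most 1.16 FPKM (fragments scaled for gene length and library size) in any library, whereas thalamic and hindbrain genes marked the samples as labelled.

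The first question was which genes differ between thalami of CFA and saline rats. Immune, microglial and reactive astrocyte genes were far higher in the 3 CFA libraries, and more rises than falls passed. Lcn2, which encodes the iron-binding acute-phase protein lipocalin 2, rose from 1.12 ± 0.58 to 319 ± 53.8 FPKM (mean ± SD, n = 3 per group), a log2 change of 7.26 ± 0.24 (SE). Cxcl13, a chemokine that attracts B cells, rose from 0.377 ± 0.227 to 92.9 ± 25.1 FPKM. Cd74, the invariant chain of MHC class II, rose from 12.5 ± 2.78 to 674 ± 90.3 FPKM. Complement C3 rose from 5.04 ± 0.97 to 161 ± 31.6 FPKM, and the lysozyme gene Lyz2 of myeloid cells rose from 26.6 ± 8.87 to 579 ± 43.5 FPKM. The adjusted p by limma was 0.000182 for Lcn2 and Cd74, 0.000212 for Cxcl13 and C3 and 0.000535 for Lyz2, and every CFA library exceeded every saline library for these 5 genes.

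**Figure D1:**
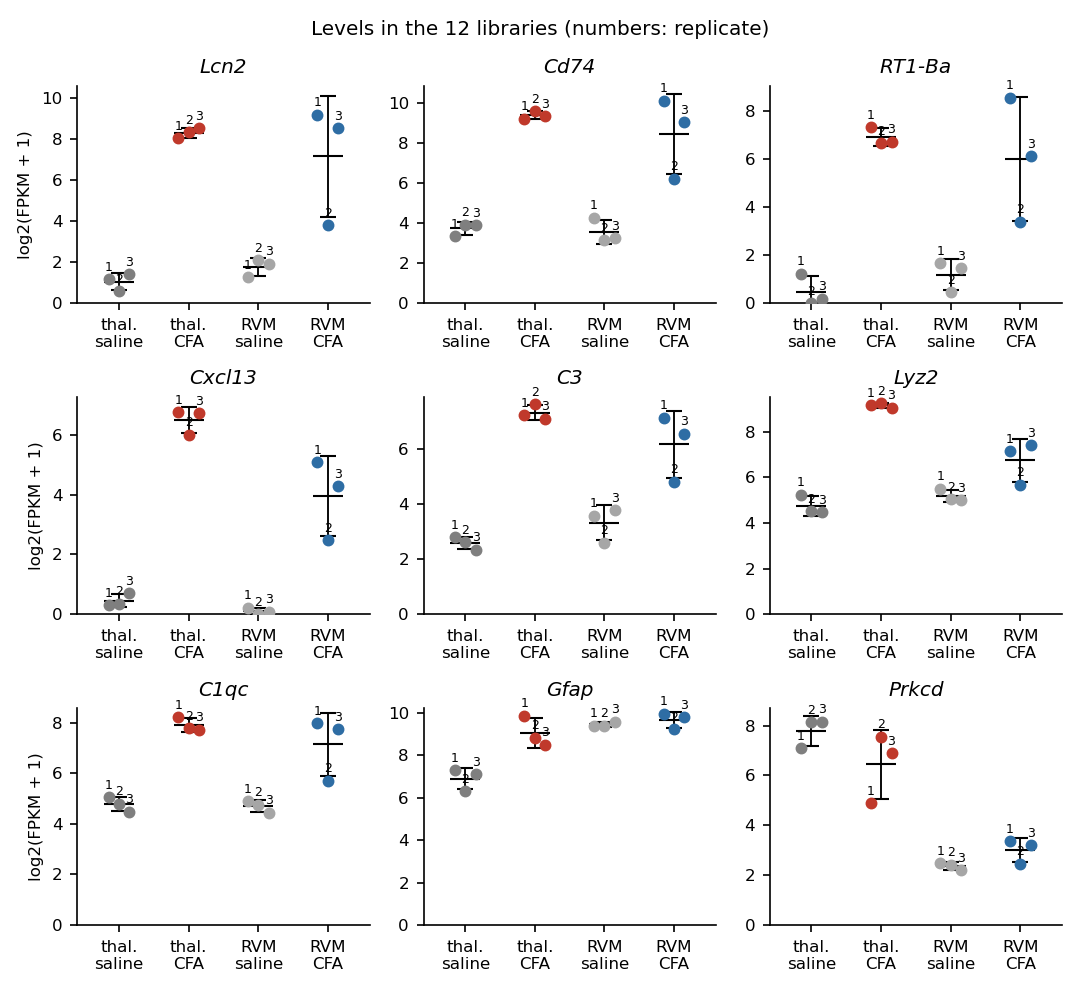
Levels of 9 genes in the 12 libraries, as log2(FPKM + 1), with points numbered by replicate and bars giving mean ± SD of the 3 libraries of a group. For the immune genes the 3 thalamus CFA libraries lie together above all saline libraries (Lcn2 319 ± 53.8 against 1.12 ± 0.58 FPKM), while RVM CFA library 2 lies below the other RVM CFA libraries.

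In the table these genes are ENSRNOG00000013973 (Lcn2, chromosome 3, 11414186 to 11417546), ENSRNOG00000024899 (Cxcl13, chromosome 14, 15253125 to 15258207), ENSRNOG00000018735 (Cd74, chromosome 18, 56071478 to 56080849), ENSRNOG00000046834 (C3, chromosome 9, 9721105 to 9747167) and ENSRNOG00000005825 (Lyz2, chromosome 7, 60335969 to 60341264). The values are sums over whole genes, so exons and untranslated regions were not told apart, and the genome build of these coordinates is not given in the sources used here. Others among the 12 largest rises were RT1-Ba, RT1-Da, RT1-Db1 and RT1-Bb, which encode MHC class II chains, with log2 changes of 6.46, 5.19, 4.97 and 4.20. RT1 genes belong to a family of close copies, and reads shared among them leave the split between members uncertain. Plac8, Gpnmb and the complement inhibitor gene Serping1 completed the 12, with log2 changes of 5.03, 4.33 and 4.26. The calls of all 12 held in each of the 6 fits that left out 1 library.

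In all, 605 of 14722 genes with a mean of at least 1 FPKM passed an adjusted p of 0.05, 565 higher and 40 lower in CFA. Of these, 470 rises and 7 falls exceeded 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. At an unadjusted p of 0.05, 3152 genes differed, 1492 higher and 1660 lower, against 736 expected with no effect. The groups did not overlap for 29% of the genes, against 10% by chance, with CFA above saline for 1796 genes and below it for 2469. The excess of rises thus holds for the genes that passed and not for all that differed. With the replicate number as a block 755 genes were higher and 583 lower, with all 12 libraries in a single model 1100 and 832, and with quality weights 800 and 210. Rescaling every library to the same FPKM total moved the median log2 change of all genes from -0.08 to 0.07 and gave 768 genes, 754 higher and 14 lower, so changes below about that shift depend on the scaling. Leaving out thalamus saline library 2 or 3 lowered the count from 605 to 320 or 309. Without CFA libraries 1 and 2 together, which carried choroid plexus transcripts, the count was 98 (97 higher), and 89 of these were among the 605. That fit sets 1 CFA library against 3 saline libraries, so its spread comes from saline alone. Without saline 1 and CFA 1 together, the libraries with the lowest thalamic markers of their groups, 738 genes passed, 494 higher and 244 lower, and 433 of these were among the 605.

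Antigen presentation genes rose in 14 of 16 cases, 15 when adjusted over the list alone, with a median log2 change of 2.84. All 8 complement genes rose, also when adjusted over the list alone, with a median of 2.78. C1s and C2, proteases of the classical pathway, had log2 changes of 3.12 and 2.90. Among 15 microglia and macrophage markers 12 rose, 13 when adjusted over the list alone, with a median of 1.65. The lysosomal marker Cd68 rose from 0.971 ± 0.146 to 27.0 ± 7.24 FPKM, the complement component C1qc from 26.8 ± 5.30 to 243 ± 46.6 FPKM, and Aif1, the microglial marker Iba1, from 7.56 ± 1.81 to 36.5 ± 4.85 FPKM. Of 23 cytokine, chemokine and NF-kB genes 15 rose, and 20 rose and 1 fell when adjusted over the list alone, with a median of 1.57. Ccl2, which attracts monocytes, rose from 0.104 ± 0.124 to 16.2 ± 8.77 FPKM and the interleukin Il1b from 0.158 ± 0.106 to 10.1 ± 3.51 FPKM. The filter is a mean over all 6 libraries, so members low in saline, such as these, were tested through their CFA levels. Over the saline libraries of both regions 11 antigen presentation, 6 complement and 11 cytokine genes reached it. The counts, medians and set tests of these lists thus lean towards rises. Interferon response genes rose in 11 of 21 cases, 20 when adjusted over the list alone, with a median of 1.25. The immunoproteasome subunits Psmb9 and Psmb8 had log2 changes of 2.43 and 2.40, and the transcription factor Irf1 had 2.34. Ifitm3, an interferon-induced membrane protein gene, had a log2 change of 2.32 and lost its call without saline library 3 (2.30).

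Reactive astrocyte genes rose in 11 of 13 cases, and in all 13 when adjusted over the list alone, with a median log2 change of 2.39. Over the saline libraries of both regions 9 members reached the filter, so these counts lean towards rises too. After Lcn2 the largest were Timp1, an inhibitor of matrix metalloproteinases, from 2.16 ± 1.01 to 59.1 ± 33.2 FPKM, and Cp, the copper-carrying ferroxidase ceruloplasmin, from 2.70 ± 1.21 to 39.9 ± 9.17 FPKM. Gfap, the intermediate filament of astrocytes, rose from 124 ± 39.7 to 585 ± 307 FPKM (log2 2.16 ± 0.41, limma adjusted p = 0.0405). That call was lost in each of the 6 fits without 1 library, with log2 changes between 1.76 and 2.44. None of 12 general astrocyte markers passed, and their median was -0.23. Leukocyte genes on the blood list, S100a9 and S100a8, which encode calprotectin of neutrophils and monocytes, rose by log2 changes of 3.17 and 2.58, 2 of 7 members, also when adjusted over the list alone. The call of S100a9 was lost in 3 and that of S100a8 in 5 of the 6 fits without 1 library, with log2 changes down to 2.81 and 2.21. Among 14 glucocorticoid response genes 3 rose, the metallothioneins Mt2A and Mt1 and the transcription factor Cebpd, with log2 changes of 2.34, 1.99 and 2.11, and Ddit4 was lower when adjusted over the list alone (log2 -0.54). The Mt2A and Mt1 calls were lost in 5 and 3 of the 6 fits without 1 library, with log2 changes down to 1.98 and 1.79.

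As a set against all other genes, these 6 lists, antigen presentation, microglia, cytokines, interferon response, reactive astrocyte and complement, had adjusted p-values between 8.86e-22 and 2.09e-15 by limma's camera with a preset correlation. With an estimated correlation none passed, with an adjusted p = 0.0824 for 5 of them and 0.204 for interferon response. By fry, which asks whether the genes of a list move 1 way on balance, the 6 passed, with adjusted p-values between 0.000448 and 0.00961. The blood and glucocorticoid lists were not called by camera, with adjusted p-values of 0.451 and 0.598.

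**Figure D2:**
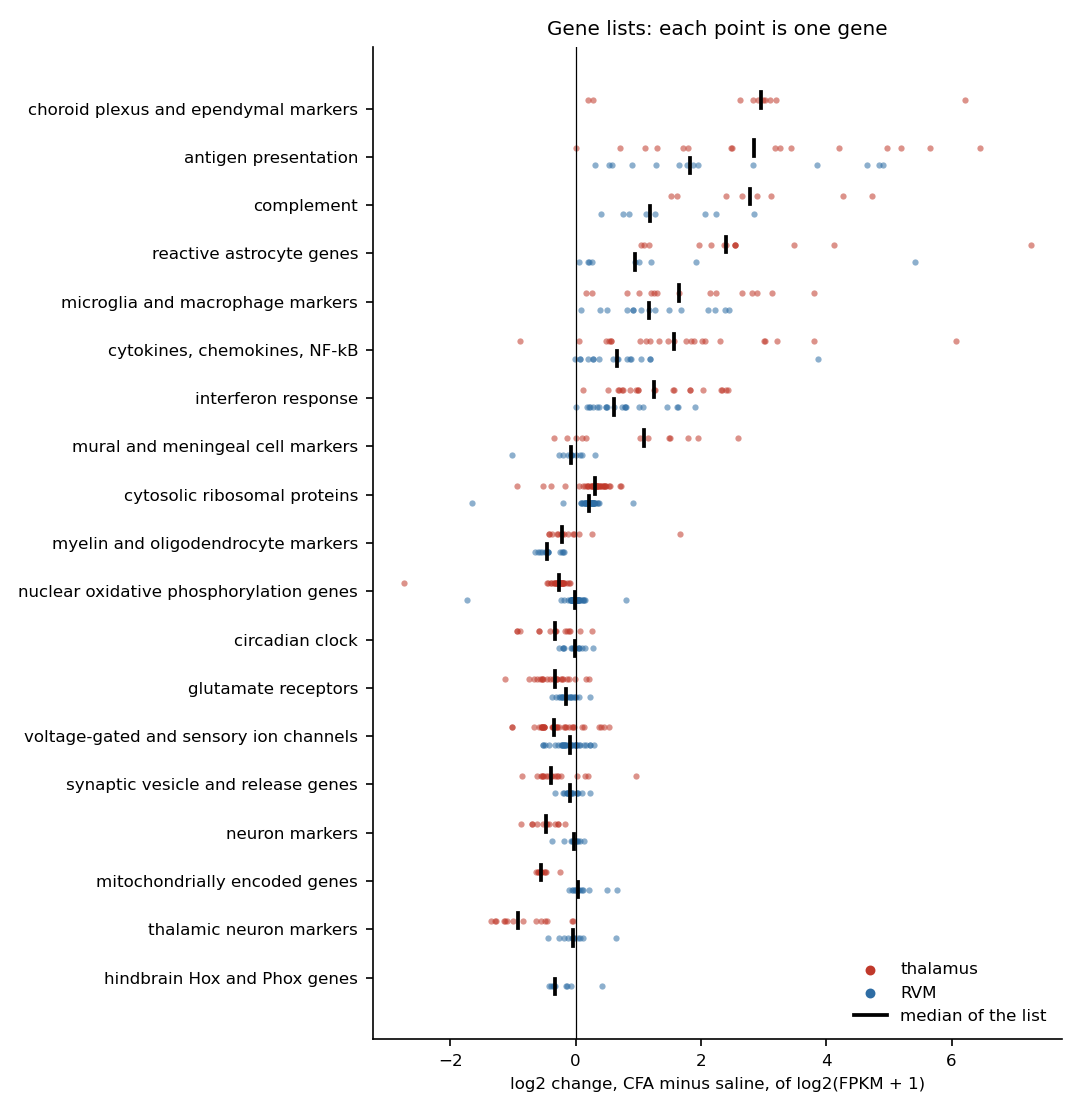
Log2 change with CFA of each measured gene in the lists called in at least 1 region, thalamus in red and RVM in blue, with a black bar at the median of a list. Lists with fewer than 5 measured genes in a region are left out there. The immune and reactive astrocyte lists lie to the right of 0 in both regions (antigen presentation medians 2.84 and 1.83), and the myelin list in RVM lies wholly to the left (median -0.45).

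Falls that passed in the thalamus were fewer and smaller than the rises. The largest was in Kansl2, a subunit of a histone acetyltransferase complex, from 8.21 ± 2.47 to 1.56 ± 1.18 FPKM. Next came Tnks2, which encodes tankyrase 2, from 4.29 ± 2.29 to 0.597 ± 0.0275 FPKM. The Tnks2 entry is listed on a sequence not assigned to a chromosome, and whether it stands for the whole gene was not tested. Both genes also varied widely among RVM libraries of the same treatment. Kansl2 was at 6.25 ± 4.95 FPKM in RVM saline and 7.32 ± 4.82 in RVM CFA, and Tnks2 at 1.28 ± 0.827 and 1.09 ± 1.20. Variation between samples apart from treatment thus stays open as a source of both falls. Mir770, a microRNA precursor listed at chromosome 6, 133682957 to 133683050, fell from 80.9 ± 13.1 to 33.2 ± 4.19 FPKM. It lies within a longer noncoding transcript, and reads of host and precursor were not told apart. The clock gene Per1 fell from 16.4 ± 1.33 to 8.57 ± 1.98 FPKM, and Stx1a, a membrane protein of synaptic vesicle fusion, from 44.0 ± 8.83 to 23.6 ± 2.92 FPKM. Igsf1, Arpp21, Kcnmb4, Fjx1, Krt2, Zfp365 and Fbxl16 made up the 12, with log2 changes between -0.91 and -0.66. Of the 12 calls only that of Mir770 held in all 6 fits without 1 library, while the log2 changes stayed close to those of the full fit, between -2.26 and -1.58 for Kansl2, -1.04 and -0.74 for Per1 and -0.72 and -0.58 for Fbxl16.

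Neuronal lists were lower as sets in the thalamus of CFA rats, with few single genes past the threshold. These calls are by camera with the preset correlation. None of these 6 lists passed with an estimated correlation (adjusted p = 0.473 to 0.751) or by fry (adjusted p = 0.056 to 0.367). All 12 neuron markers had negative log2 changes, with a median of -0.47, and none passed over all genes or when adjusted over the list alone (Syt1 -0.70, Stmn2 -0.52). Of 18 synaptic vesicle genes Stx1a alone fell, and 2 when adjusted over the list alone (Syn1 -0.44). Of 36 ion channel genes Cacna2d1, the calcium channel subunit bound by gabapentin, fell from 19.7 ± 1.91 to 13.5 ± 0.599 FPKM, and 0 when adjusted over the list alone. Its call was lost in 5 of the 6 fits without 1 library (log2 -0.59 to -0.45). Of 22 glutamate receptor genes 20 had negative changes and 0 passed, over all genes or over the list alone (Grin2c -0.62, Grin1 -0.52). All 14 thalamic neuron markers had negative changes with a median of -0.92 and 0 passed either way. Prkcd was at 233 ± 83.5 FPKM in saline and 111 ± 79.2 in CFA. Of 15 clock genes Per1 fell, also when adjusted over the list alone. By camera with the preset correlation the adjusted p was 0.00946 for neuron markers, 0.00764 for synaptic vesicle genes, 0.0187 for ion channels and for glutamate receptors, 0.0343 for thalamic markers and 0.0216 for clock genes. With an estimated correlation all were lost, with adjusted p-values of 0.661, 0.658, 0.661, 0.473, 0.751 and 0.661. Over the 3 other scalings their medians came as close to 0 as -0.31, -0.23, -0.20, -0.23, -0.78 and -0.21, in the same order. Leaving out CFA library 1 moved the median of neuron markers to -0.30 and ended the calls of ion channels (median -0.20), thalamic markers (-0.35) and clock genes (-0.17). Those lists were also lost without saline library 3 (ion channels -0.25) or saline library 2 (thalamic markers -0.58, clock genes -0.30), the last 2 also after quantile normalization (-0.82 and -0.31), and the glutamate receptor call without saline 1 (-0.28) or CFA 3 (-0.42), with a median of -0.52 without CFA 2. Without CFA libraries 1 and 2 together, with a single CFA library left, 8 of the 17 list calls in thalamus were lost, among them neuron markers (-0.25), synaptic vesicle genes (-0.24), nuclear oxidative phosphorylation genes (-0.12) and choroid plexus markers (0.22).

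Markers of neighbouring tissue varied among the same thalamus libraries. Choroid plexus and ependymal markers had a median log2 change of 2.95 with none of 10 past the threshold over all genes or over the list alone (camera adjusted p = 0.000776, adjusted p = 0.658 with an estimated correlation and 0.219 by fry). The median was 1.85 without CFA library 1. Ttr, the transthyretin gene abundant in choroid plexus, chosen after its values were seen, was at 9934, 2361 and 5.50 FPKM in CFA libraries 1, 2 and 3 and at 18, 2.31 and 4.91 FPKM in saline. Folr1 was at 39.2 ± 40.0 FPKM in CFA and 2.59 ± 1.83 in saline. Mural and meningeal markers had a median of 1.09 (camera adjusted p = 0.0276, adjusted p = 0.741 with an estimated correlation and 0.512 by fry), none of 12 passed either way, and the call was lost without saline 3 (1.08) or CFA 1 (0.31), after rescaling to the same total (1.33) and with median-of-ratios scaling (1.14). Col3a1 was at 33.3 ± 28.1 FPKM in CFA and 3.62 ± 2.20 in saline. Within each thalamus group the mean of the thalamic markers was lowest in library 1. Tcf7l2, a transcription factor of thalamic neurons, was at 44.9 FPKM in saline 1 and 28.9 in CFA 1, against 69.7 to 130 FPKM in the other thalamus libraries. Slc17a7, more abundant in cortex than in most of the thalamus, was highest in the same libraries, at 100.1 and 225 FPKM against 22.4 to 57.8 FPKM. Saline library 2 stood apart in other forebrain neighbour markers. Gpr151 was at 1.34 FPKM there and at 22.4 to 33.8 in the other thalamus libraries, and Pou4f1 at 0.298 against 6.45 to 8.52. Oxt was at 80.4 FPKM in saline 2, 11.5 in CFA 2 and at most 0.113 in the rest, and Avp at 21.4 in saline 2 against at most 0.787. Tcf7l2, Slc17a7, Gpr151, Pou4f1, Oxt and Avp were named here after their values were seen.

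**Figure D3:**
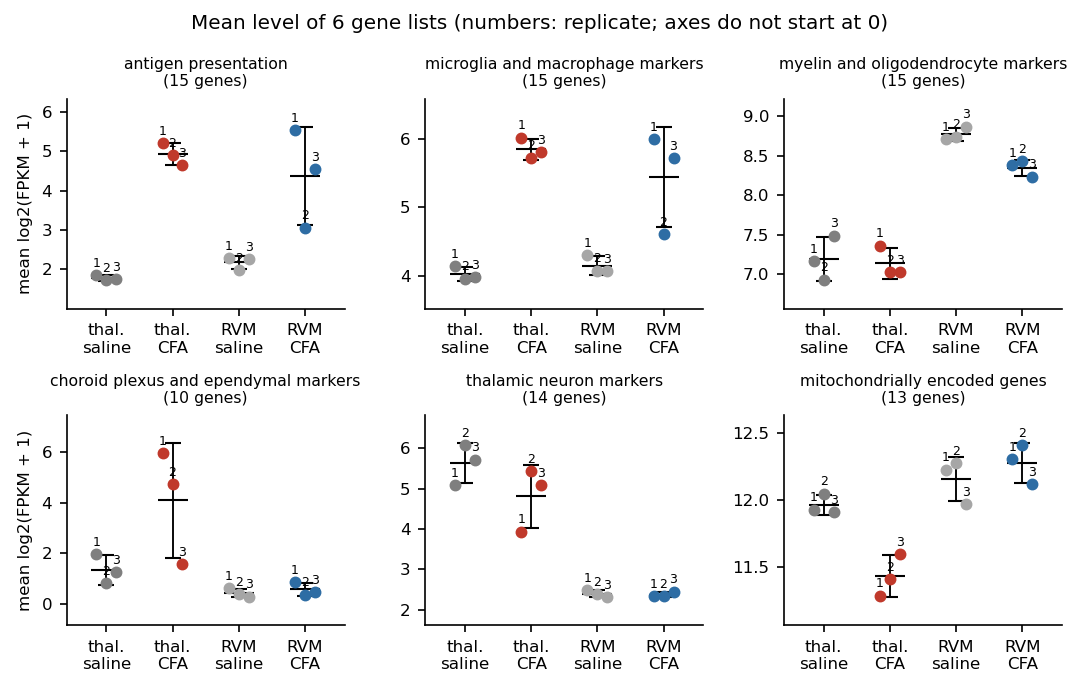
Mean log2(FPKM + 1) of 6 gene lists in each library, numbered by replicate, with mean ± SD of the 3 libraries of a group; the axes do not start at 0. Antigen presentation genes are higher in every CFA library than in the saline libraries of its region, choroid plexus markers are high in thalamus CFA libraries 1 and 2 and not in 3, and myelin markers are lower in the 3 RVM CFA libraries.

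Ribosomal protein genes were higher and genes of respiration lower as sets in the thalamus by camera with the preset correlation. None of these 3 lists passed with an estimated correlation (adjusted p = 0.488 to 0.661). By fry the ribosomal and mitochondrial lists passed (adjusted p = 0.0355 and 0.0193) and the nuclear list did not (0.137). The ribosomal list had a median log2 change of 0.31. Of 39 measured genes 3 rose (Rplp0 0.71, Rps2 0.55, Rpl10 0.48), and 23 when adjusted over the list alone. Each of these calls was lost in at least 4 of the 6 fits without 1 library, and such genes have many processed copies in the genome. Mitochondrially encoded genes had a median of -0.56, and all 13 were negative. CYTB, the cytochrome b gene, fell from 8445 ± 197 to 5579 ± 266 FPKM (limma adjusted p = 0.0481), a call lost in each of the 6 fits without 1 library (log2 -0.63 to -0.56), and 12 were lower when adjusted over the list alone. The share of reads of all genes listed on the mitochondrial chromosome, of any biotype, was 9.71% ± 0.21 in saline and 7.53% ± 0.68 in CFA. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allow. All 36 nuclear oxidative phosphorylation genes were negative, with a median of -0.27, and none passed over all genes or over the list alone. Camera gave adjusted p-values of 3.98e-12, 1.07e-07 and 6.83e-06 for the ribosomal, mitochondrial and nuclear lists, and 0.488, 0.488 and 0.661 with an estimated correlation. After quantile normalization the mitochondrial median was -0.16 and its call was lost, and the nuclear median came as close to 0 as -0.10 over the 3 other scalings.

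The remaining lists were not called in the thalamus. Immediate early genes had a median log2 change of -0.05, with 0 of 20 past the threshold and Dusp1 lower when adjusted over the list alone (log2 -1.25). Fos was at 27.6 ± 9.04 FPKM in saline and 15.8 ± 7.78 in CFA (limma adjusted p = 0.281). Among 7 opioid genes 0 passed, over all genes or over the list alone. The mu receptor Oprm1 was at 5.68 ± 2.83 FPKM in saline and 2.47 ± 1.25 in CFA, and the peptide precursors Penk and Pdyn at 20.7 ± 13.2 and 3.80 ± 2.65 against 13.9 ± 8.32 and 2.56 ± 1.36. The neuropeptide list had no member past the threshold either way (Tac1 22.4 ± 7.71 in saline and 33.4 ± 8.80 in CFA, Bdnf 3.68 ± 1.12 and 2.65 ± 0.969), although fry gave the list an adjusted p = 0.0176. Tph2 and Calca were below the filter in thalamus, at no more than 1.10 and 1.19 FPKM in any library. None of the myelin, oligodendrocyte precursor, endothelial, forebrain neighbour, serotonergic, noradrenergic and cholinergic, serotonin receptor, GABA and glycine, heat shock and growth factor genes passed over all genes or over their list alone. Camera adjusted p-values of these lists and of the astrocyte, immediate early, opioid and neuropeptide lists lay between 0.149 and 0.78. Retina, hindbrain and cerebellar lists had fewer than 5 measured genes and were not tested.

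The same question was asked in RVM. Immune genes were again higher in CFA as sets, myelin genes were lower as a set, and no single gene passed over all genes. These set calls are by camera with the preset correlation. None passed with an estimated correlation (smallest adjusted p = 0.463) or by fry (smallest adjusted p = 0.0887). Cd74 was at 11.5 ± 5.82 FPKM in saline and 571 ± 519 in CFA, and Lcn2 at 2.47 ± 0.958 and 322 ± 288 FPKM. The 3 CFA libraries lay far apart. Library 2 was lowest, with 73.6 FPKM of Cd74 and 12.8 of Lcn2, while libraries 1 and 3 held 1108 and 530 of Cd74 and 583 and 369 of Lcn2. Ugt8, which makes the myelin lipid galactosylceramide, was at 403 ± 64.2 FPKM in saline and 254 ± 14.3 in CFA.

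Of 14289 genes tested in RVM 0 passed by limma, and the smallest adjusted p was 0.242. At an unadjusted p of 0.05, 2030 genes differed against 714 expected, 847 higher and 1183 lower, and 0 passed by voom on the recovered reads. The groups did not overlap for 19.8% of the genes, against 10% by chance, with CFA above saline for 1039 genes and below it for 1786. Leaving out RVM CFA library 2 gave 477 genes, 390 higher and 87 lower. Leaving out saline 1, saline 2 or CFA 1 gave 1, 1 and 2 genes. The genes with the smallest unadjusted p upwards were Spint1 (log2 0.84), Cxcl13 (3.86), Lrg1 (2.21), C5ar2 (1.42), Gpx1 (0.41), Cd37 (1.37), Plac8 (4.64), Cd74 (4.91), Clec4a3 (2.41), S100a9 (1.75), S100a8 (0.86) and Tagap (0.98). Downwards they included Derl3 (log2 -1.69), Secisbp2l (-0.46), Col9a3 (-0.41), Sema4d (-0.76), Selenoi (-0.44), Gjc3 (-0.52), Cldn11 (-0.48), Tspan15 (-0.34), Cntn1 (-0.28), Mog (-0.44) and a gene whose symbol reads as a date. The p-value adjusted over all genes by limma was 0.242 for each of these.

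In RVM too, members low in saline reached the filter through their CFA levels, and the members tested differ in part from those in thalamus. Antigen presentation genes had a median log2 change of 1.83 in RVM. All 14 were positive, and 10 were higher when adjusted over the list alone, with 0 over all genes (RT1-Ba 4.84, RT1-Da 4.65). Microglia and macrophage markers had a median of 1.18, with 12 of 15 higher when adjusted over the list alone (C1qc 25.3 ± 4.14 in saline and 172 ± 106 FPKM in CFA, Aif1 9.63 ± 1.62 and 33.7 ± 21.6). Complement genes had a median of 1.19, with 7 of 8 higher when adjusted over the list alone (C3 9.60 ± 4.04 and 86.5 ± 56.4 FPKM). Of 17 cytokine and NF-kB genes 7 were higher when adjusted over the list alone, with a median of 0.65 (Il1b log2 1.19, Tlr2 1.19). Of 9 reactive astrocyte genes 2 were, with a median of 0.94 (Lcn2 5.42, Cp 1.92), and Gfap was at 709 ± 55.8 FPKM in saline and 830 ± 207 in CFA (log2 0.20). All 21 interferon response genes were positive, with a median of 0.61 and 0 past the threshold when adjusted over the list alone (Psmb9 1.63, Irf1 1.45). That median was 0.26 without CFA library 3 and 1.06 without CFA library 2. Camera gave adjusted p-values between 1.52e-11 and 4.63e-05 for these 6 lists. With an estimated correlation all were lost, with an adjusted p = 0.463 for 5 of them and 0.665 for interferon response.

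All 15 myelin and oligodendrocyte markers were lower in RVM of CFA rats, and 12 passed when adjusted over the list alone, with 0 over all genes. Their median log2 change was -0.45, and it lay between -0.50 and -0.40 in the fits without 1 library. Ugt8 had a log2 change of -0.65. Tspan2 was at 148 ± 10.0 FPKM in saline and 99.6 ± 11.7 in CFA, and Mal at 410 ± 33.9 and 288 ± 70.7 FPKM. Camera gave an adjusted p = 1.21e-11, and 0.463 with an estimated correlation. Of 39 ribosomal protein genes 21 were higher when adjusted over the list alone, with a median of 0.22 (Rpl30 0.92, Rplp0 0.35), an adjusted p = 1.35e-14 and 0.463 with an estimated correlation. Glutamate receptor genes had a median of -0.15 and 0 of 21 past the threshold either way (Grin2a -0.37). Their camera adjusted p was 0.0117, or 0.463 with an estimated correlation, and the call was lost without CFA 1 (median -0.12). Hindbrain Hox and Phox genes had a median of -0.33, with 1 of 9 lower when adjusted over the list alone (Hoxb3 13.3 ± 0.836 and 10.2 ± 0.173 FPKM). Their adjusted p was 0.0403, or 0.463 with an estimated correlation, and the call was lost without saline 1 (-0.22), CFA 1 (-0.25) or CFA 3 (-0.20). By fry 0 of 33 lists passed in RVM, with a smallest adjusted p of 0.0887.

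As no gene of any kind passed over all genes in RVM, the absence of calls is not particular to genes tied to descending pain control. Tph2, the enzyme of serotonin synthesis in neurons, was at 56.3 ± 10.5 FPKM in saline and 42.6 ± 7.74 in CFA (log2 -0.39, limma adjusted p = 0.36). Of 9 serotonergic markers 1 was lower when adjusted over the list alone (Gch1 -0.44), as was 1 of 8 serotonin receptors (Htr1b -0.38) and 5 of 23 GABA and glycine genes (Gabra4 -0.55, Gabrg1 -0.36). Penk was at 143 ± 10.2 and 152 ± 11.5 FPKM, Pdyn at 3.58 ± 0.428 and 4.27 ± 0.708, Fos at 8.40 ± 1.46 and 8.74 ± 1.26, Calca at 23.1 ± 6.92 and 16.8 ± 6.48, and Bdnf at 5.01 ± 1.05 and 3.82 ± 0.307, in saline and CFA, and Tac1 had a log2 change of -0.25. The adjusted p for these 6 genes by limma lay between 0.395 and 0.907. Oprm1 was below the filter in RVM, at no more than 0.606 FPKM in any library. When adjusted over the list alone, 2 of 8 blood markers were higher (S100a9 and S100a8), and 1 oligodendrocyte precursor (Gpr17 -0.58), 1 mural and meningeal, 1 thalamic and 1 cerebellar gene were lower. The other lists held no gene past the threshold in either way, and camera adjusted p-values of the lists not called lay between 0.087 and 0.825. The retina, choroid plexus and cerebellar lists had fewer than 5 measured genes and were not tested as sets.

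The difference between the regions in their response to CFA was tested as the interaction of region and treatment. Of 13738 genes 0 passed by limma, with a smallest adjusted p of 0.27, 1560 at an unadjusted p of 0.05 against 687 expected, and 0 by voom. The genes with the smallest p towards a higher signed change in thalamus were Il1rn, the interleukin 1 receptor antagonist, and the lipopolysaccharide co-receptor Cd14. Il1rn went from a mean of 0.235 to 13.7 FPKM in thalamus and from 0.601 to 1.81 in RVM, and Cd14 from 0.690 to 12.7 and from 1.16 to 3.01. Gpnmb, Slamf9, Prcp and Fabp4 came next, with log2 differences of 3.32, 1.66, 0.96 and 1.82. In the other direction stood Etv5 (log2 difference -0.95), Git1 (-0.59), Camk2n1 (-0.85), Wdtc1 (-0.38), Mir2861 (-0.72) and Dynlt3 (-0.52). All 12 had an adjusted p = 0.27 by limma. The difference for Gfap was 1.97 ± 0.49 (limma adjusted p = 0.317). Those for Tac1, Aif1, Bdnf, Pdyn, Penk and Fos were 0.84, 0.65, -0.06, -0.56, -0.60 and -0.90 (limma adjusted p between 0.439 and 0.944). With the replicate number as a block 29 genes passed, 9 with a positive and 20 with a negative difference. Leaving out thalamus saline 1 gave 15 genes and leaving out thalamus CFA 2 gave 1. Of 31 lists 15 passed by limma's camera with the preset correlation, 9 with a positive and 6 with a negative median of the signed difference, thalamus minus RVM. A negative difference is not a smaller change. Neuron markers had a median log2 change of -0.47 in thalamus and -0.02 in RVM, and myelin markers, with a positive difference, -0.22 and -0.45. With an estimated correlation 0 passed, with a smallest adjusted p = 0.32, and by fry 0 passed, with a smallest adjusted p = 0.105.

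Genes raised in the thalamus were mostly positive in RVM too, an overlap computed after the data were examined. Of the 565, 496 were tested in RVM, and 488 of them (98.4%) had a positive log2 change there, against 43.9% of all genes tested. At an unadjusted p of 0.05, 343 (69.2%) were higher in RVM, against 6.01% of all genes. The comparisons share no library. The labels do not say whether the samples of both regions came from the same rats, so the overlap may not be an independent replication. The median log2 change of the 496 genes was 1.49 in thalamus and 0.78 in RVM. The genes were selected for their change in thalamus, so a smaller median in RVM is expected from the selection alone. Of 39 lowered genes tested 30 (76.9%) were negative, against 56.1% of all. Across all 13738 genes, which are not independent replicates, Pearson's r was 0.608 and Spearman's rho 0.354. The mean log2 level of the 496 genes was higher in the 3 RVM CFA libraries by 0.88, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow. The libraries were unlike, with median differences from the saline mean of 1.14, 0.20 and 0.99 in RVM CFA 1, 2 and 3.

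**Figure D4:**
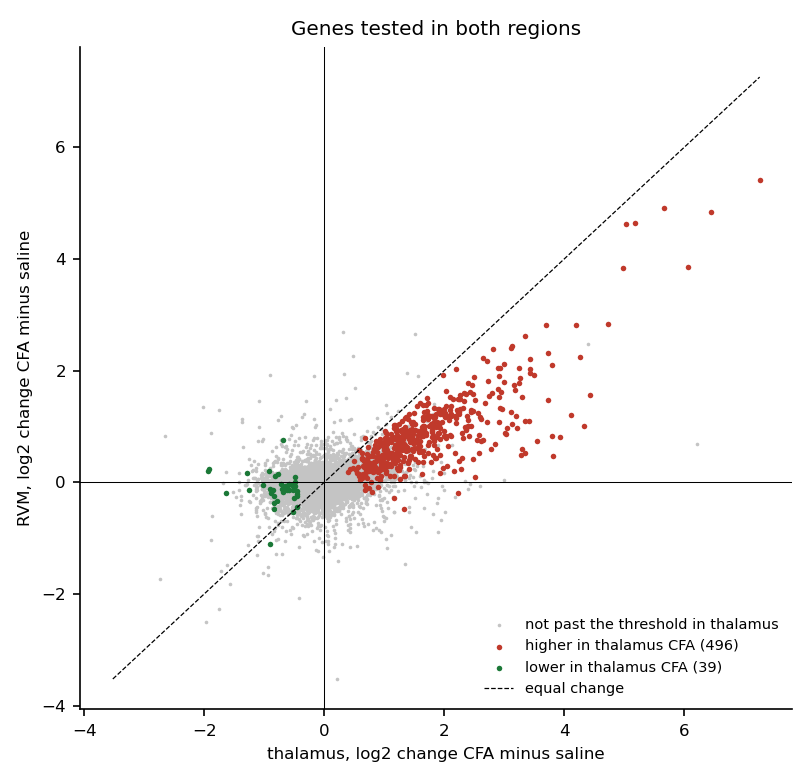
Log2 change with CFA in thalamus (x axis) and RVM (y axis) of the 13738 genes tested in both, 1 point per gene. The 496 genes raised in thalamus (red) lie almost wholly above 0 in RVM (488 of them), with medians of 1.49 and 0.78, of which the thalamus value is raised by the selection, and 30 of the 39 lowered genes (green) are negative in RVM.

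Saline libraries of the regions differed in 6523 of 14396 genes, 3250 higher and 3273 lower in thalamus. Prkcd, a protein kinase C of thalamic relay neurons, was at 233 ± 83.5 FPKM in thalamus and 4.18 ± 0.537 in RVM (n = 3 each). Gabrd, Yjefn3 and Necab1 were also among the largest, with log2 differences between 5.12 and 5.42. Tph2 was at 0.214 ± 0.128 FPKM in thalamus and 56.3 ± 10.5 in RVM. Trh, the thyrotropin-releasing hormone gene, was at 2.85 ± 1.75 and 156 ± 52.0 FPKM, and the glycine transporter Slc6a5 of glycinergic neurons at 0.474 ± 0.157 and 53.6 ± 3.17 FPKM. Crh and Lamp5 were also higher in RVM, with log2 differences of -4.70 and -4.54. The adjusted p by limma was at most 0.00138 for these 9 genes. After rescaling every library to the same total the median difference of all genes moved from -0.02 to 0.14, and the split became 4572 higher and 2014 lower.

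Of 14 thalamic markers 13 were higher in thalamus, 14 when adjusted over the list alone (Tcf7l2 log2 4.98, Ptpn3 4.54). All 8 Hox and Phox genes tested were higher in RVM, also when adjusted over the list alone. Hoxb2 was at 16.3 ± 1.51 FPKM there and listed at 0 in the 3 thalamus saline libraries. Of 9 serotonergic markers 7 were higher in RVM and 1 in thalamus, also over the list alone, with the serotonin transporter Slc6a4 (log2 -4.26) among the 7. Myelin markers were higher in RVM for all 15, also over the list alone, with Mbp at 11811 ± 613 FPKM there and 2638 ± 569 in thalamus. Gfap was at 709 ± 55.8 FPKM in RVM and 124 ± 39.7 in thalamus (limma adjusted p = 0.000496). Glutamate receptors were higher in thalamus for 17 of 22 genes and lower for 1, counts that were the same when adjusted over the list alone (Grm4 2.61, Grin2b 2.39). Ion channels were higher for 16 and lower for 2 of 36, either way (Hcn4 2.42, Cacna1g 2.17, Scn4b -2.16). Of 16 neuropeptide genes 3 were higher and 7 lower in thalamus, either way. Cck, the cholecystokinin gene, was at 397 ± 135 FPKM in thalamus and 26.2 ± 3.54 in RVM, while Calca, the gene of calcitonin gene-related peptide, was at 1.02 ± 0.167 and 23.1 ± 6.92. Clock genes were higher in thalamus for 12 of 15, either way (Hlf 2.38, Npas2 1.83). Interferon response genes were lower in thalamus for 14 of 20, 17 when adjusted over the list alone (Ifi27 -1.66). Penk and Tac1 were lower in thalamus (log2 -2.90 and -1.35), and Oprm1 and Fos higher (2.03 and 1.57). Bdnf, Aif1 and Pdyn did not pass (log2 -0.37, -0.32 and -0.07, limma adjusted p between 0.189 and 0.893). No set test was planned for this comparison.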

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

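The tests of choroid plexus tissue, scaling, blood, a wrong label, depth, white matter and dilution by RNA of other cells were chosen after the result was seen. Those of the amount of RVM tissue and of dilution by immune RNA were written down before their values were seen.

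The test of the difference between the regions' CFA effects singled out 15 gene lists, by limma's camera with a preset correlation. None passed with an estimated correlation. Values are median log2 differences, thalamus minus RVM. Reactive astrocyte genes and complement each differed by 1.57 (adjusted p = 4.25e-08 by camera, 0.32 with an estimated correlation, for both). Mural and meningeal markers differed by 1.3, antigen presentation by 1.01, cytokine and NF-kB genes by 0.68, interferon response by 0.503, microglia and macrophage markers by 0.438, myelin by 0.215 and ribosomal proteins by 0.115. Nuclear oxidative phosphorylation genes differed by -0.26, synaptic vesicle genes by -0.345, clock genes by -0.364, neuron markers by -0.432, mitochondrially encoded genes by -0.58 and thalamic markers by -0.748. Camera's adjusted p lay between 6.61e-11 and 0.00454 for all 15, and between 0.32 and 0.648 with an estimated correlation. These list differences were not tested with a library left out. In the RVM fits without a single library the medians reached 1.06 for interferon response, 1.55 for microglia and 2.29 for antigen presentation. In the full thalamus fit they were 1.25, 1.65 and 2.84. Complement, reactive astrocyte and cytokine genes reached 1.62, 1.22 and 0.857 in RVM, against 2.78, 2.39 and 1.57 in thalamus. The interferon and microglia differences may thus rest on single RVM libraries.

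Immune, microglial and reactive astrocyte genes were higher in the 3 thalamus CFA libraries, of which libraries 1 and 2 held choroid plexus transcripts. With the choroid plexus marker level as a covariate the genes that had passed upwards kept a median log2 change of 1.4, against 1.54 without it, with fewer calls (142 upwards), since the covariate varies with treatment and takes up a degree of freedom. These genes passed by differing little among the CFA libraries, whose choroid plexus levels differ widely. The kept median was thus largely set by that selection and does not decide on choroid plexus tissue. CFA library 3 had a mean choroid plexus marker level of 1.58 on the log2(FPKM + 1) scale, against 0.82 to 1.97 in saline. Its antigen presentation level was 4.66, against 1.73 to 1.86. In that 1 library choroid plexus tissue does not account for the rise of this list. Under 3 other scalings at least 493 of the 565 rises passed again, which argues against scaling. The hemoglobin genes had a median log2 change of -0.534, which argues against more red cell RNA in the CFA group. Library 1 went the other way, as Hba-a1 was at 487, 192 and 126 FPKM in CFA libraries 1, 2 and 3 and at 415, 234 and 369 in saline. Hemoglobin does not measure leukocytes, so a part played by leukocytes of blood left in the tissue stays open. Whether resident cells changed or leukocytes entered the tissue stays open, as do the treatment itself and the way the tissue was dissected. A response of thalamic tissue to CFA is thus a hypothesis.

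RVM CFA library 2 lay far below libraries 1 and 3 for immune genes. A saline library with a CFA label is argued against. Library 2 lay above all 3 RVM saline libraries for 57.9% of the genes raised in thalamus, against 24.9% of all genes tested. The saline libraries were highest for 12.3% to 15.5%, each ranked with library 2 among the others, so these shares are no separate baseline. Library 2 held 19.24 M reads, the most of the 12. Its serotonergic and Hox or Phox markers differed from those of the other RVM CFA libraries by a median log2 of 0.0206. These values argue against lower depth and against less RVM tissue. A weaker response of that animal or sample stays open and was not tested.

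Myelin and oligodendrocyte markers were lower in the 3 RVM CFA libraries. The median log2 change was -0.426 or lower under 3 other scalings, which argues against scaling. In RVM CFA library 2, with the smallest immune difference, 13 of 15 markers lay below all saline libraries, but its median of -0.351 was also the smallest fall, against -0.447 and -0.515 in libraries 1 and 3, so a part played by dilution with RNA of immune cells stays open. Dilution by RNA of any other cells would lower neuron and astrocyte markers as much as myelin markers. Their median log2 change was -0.0329 (SD of 24 members 0.157) against -0.453, which argues against dilution as the whole cause. Less white matter in the CFA dissections and a biological loss of myelin transcripts cannot be told apart, because neuron and astrocyte markers, which less white matter would raise, had medians near 0, the lower of them -0.0703. Markers of the region were also lower in the CFA libraries. The median log2 change was -0.334 for Hox and Phox genes (8 of 9 negative) and -0.303 for serotonergic markers (7 of 9 negative). Another difference between the dissections thus stays open as well.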

How the results depend on the processing

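The voom fits, the fits without thalamus CFA 1 and 2 and those without thalamus saline 1 and CFA 1 were chosen after the data were examined. The planned count models were not run, as the values are FPKM. In thalamus 605 genes passed. The count was 298 with a filter at 5 FPKM (fewer genes tested), 1010 with quality weights, 1932 with all 12 libraries in a single model, 98 without CFA 1 and 2 (fewer samples, with 1 CFA library left and the spread from saline alone), 738 without saline 1 and CFA 1 (494 higher and 244 lower), and 309 to 544 when a library was left out, with 320 without saline 2 and 309 without saline 3. In RVM 0 genes passed by limma or voom (2030 at an unadjusted p of 0.05), 1 with no filter, and 0 to 477 when a library was left out, with 477 without CFA 2, 2 without CFA 1 and 1 without saline 1 or saline 2. For the interaction 0 passed by limma or voom (1560 unadjusted), and 0 to 15 when a library was left out, with 15 without thalamus saline 1 and 1 without thalamus CFA 2. The region count of 6523 lay between 4878 and 7198 when a library was left out, and was 7723 with quality weights and 5287 with a filter at 5 FPKM. Lists called in thalamus numbered 17, with 10 without CFA 1 and 2, 16 without saline 1 and CFA 1, 0 with an estimated correlation, 9 by fry and 13 to 17 when a library was left out. In RVM they numbered 10, with 0 with an estimated correlation, 0 by fry and 10 to 15 when a library was left out. Where no construction is named, the cause was not tested.

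Replicate numbers were tried as a pairing. Correlations of deviations between same-numbered saline and CFA libraries were 0.364, 0.0634 and 0.267 in thalamus and between -0.028 and -0.00505 in RVM. No pairing is thus seen in RVM. The thalamus values were all positive, and the labels do not say what the number means, so a factor shared by number stays open there. Not every sample correlated best with its own number, such as thalamus saline 2 with CFA 3 (0.312). With the replicate block 1338 genes passed in thalamus (755 higher and 583 lower), 0 in RVM, 29 for the interaction and 5765 between regions.

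Signs turned only among named genes that did not pass. Penk in thalamus went from -0.51 to 0.23 with quality weights and to 0.282 without saline 1 and CFA 1. Pdyn in thalamus ranged from -0.683 to 0.0606 when a library was left out, and Fos in RVM from -0.0807 to 0.167, with -0.00977 without CFA 2. Penk for the interaction went from -0.599 to 0.227 with quality weights. Bdnf for the interaction (-0.0588) was above 0 under 5 alternatives, at 0.0528 with every library rescaled to the same total and at most 0.126 when a library was left out. Pdyn between regions (-0.0683) was at 0.0665 with that rescaling and ranged from -0.488 to 0.255 when a library was left out. The cause was not tested. Of 103 calls of genes listed for naming 64 held under every alternative and 39 were lost under at least 1. Of 115 listed genes that did not pass 47 stayed so with their sign and 68 passed or changed sign under at least 1, among them 39 of 66 RVM genes that passed without RVM CFA 2. All 27 list calls were lost with an estimated correlation, and 8 held by fry. No called list changed the sign of its median under the 3 scalings, but some moved by over 1.5 times, with nuclear oxidative phosphorylation genes from -0.267 to -0.102, ion channels from -0.34 to -0.202, synaptic vesicle genes from -0.389 to -0.231, neuron markers from -0.466 to -0.306, clock genes from -0.324 to -0.206, ribosomal proteins from 0.314 to 0.482 and mitochondrial genes from -0.556 to -0.157. Quantile normalization ended the calls of clock, mitochondrial and thalamic marker lists in thalamus, and each of the other scalings that of mural and meningeal markers. Depth limits the genes near 0.151 to 0.215 CPM, the level of 3 reads.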

Other observations

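The lists of T cell, B and plasma cell, neutrophil, homeostatic microglia, phagocyte and proliferation genes were chosen after the data were examined. The splits of the samples were planned before.

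Some genes of lymphocytes and neutrophils were low in saline thalamus and higher in CFA. Ighm, the immunoglobulin M heavy chain gene, rose from 0.0799 ± 0.0622 to 3.67 ± 0.631 FPKM (n = 3 per group) and Cd8a, a coreceptor of cytotoxic T cells, from 0.0715 ± 0.0549 to 4.34 ± 2.65 FPKM. Csf3r, the receptor for granulocyte colony-stimulating factor, rose from 0.796 ± 0.109 to 5.27 ± 0.707 FPKM. Only 3 of 15 T cell, 2 of 10 B and plasma cell and 3 of 10 neutrophil genes reached the filter in thalamus, and these 8 passed by limma. The filter is a mean over all 6 libraries, so genes such as Ighm and Cd8a reached it through their CFA levels, and the 8 calls do not stand for the lists. In RVM 1, 1 and 3 members were tested and 0 passed, as for all genes there. S100a8 and S100a9, also members of the blood list, are expressed by monocytes as well.

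Phagocyte genes and part of the markers of resting microglia rose in thalamus. Of 15 genes of lysosomes and lipid handling 10 rose, with a median log2 change of 1.56, among them Clec7a, the receptor dectin-1, from 0.0852 ± 0.0339 to 9.46 ± 2.35 FPKM, and Lgals3, the gene of galectin-3, from 4.87 ± 1.54 to 45.8 ± 17.1 FPKM. Apoe was at 1934 ± 136 and 2272 ± 122 FPKM and did not pass. Of 9 homeostatic microglia genes 4 rose, with a median of 0.82, among them Cx3cr1 from 16.2 ± 1.19 to 38.5 ± 3.97 FPKM and P2ry12 from 10.9 ± 1.75 to 23.0 ± 1.84, while Tmem119 was at 13.5 ± 1.33 and 15.6 ± 4.66. Of 7 proliferation genes none passed, with a median of 0.86. By limma's camera the adjusted p was 9.34e-18, 1.68e-06 and 5.36e-05 for the phagocyte, homeostatic and proliferation lists, or 0.0523, 0.0215 and 0.155 with an estimated correlation. In both regions these values were adjusted over these added lists alone. That family is smaller than that of the lists fixed before, so the adjusted values of the 2 families cannot be compared. Of the homeostatic genes 4 and of the phagocyte genes 2 were also on lists fixed before. The phagocyte list holds Lyz2, Gpnmb and Cd68, whose rises had been seen when it was chosen. Its members Clec7a, Itgax and Cst7, with saline means of 0.0852, 0.0326 and 0 FPKM, reached the filter through their CFA levels. The count, median and p-values of this list were thus largely set by its choice and are no separate support. In RVM no member passed, with camera adjusted p-values of 0.00152, 0.00146 and 0.222, or 0.376, 0.376 and 0.526 with an estimated correlation. The medians of the lists were not tested against each other.

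Single libraries stood apart in the genes raised in thalamus. RVM CFA libraries 1, 2 and 3 lay above all 3 saline libraries for 96.6%, 57.9% and 94% of the 496 genes. Over all genes tested in RVM the shares were 24.5%, 24.9% and 25.7%.

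The samples were also split in other ways. In thalamus the real split gave 605 genes and the highest of the other splits 2, and 17 lists against a highest of 18, so that 1 of 10 splits gave as many genes and 2 of 10 as many lists. In RVM the real split gave 0 genes against a highest of 1, and 10 lists against a highest of 14, with 4 of 10 giving as many. Between regions 1 of 10 splits gave as many as 6523 genes, with a highest other of 1. With 10 splits no share below 0.05 can be had. The real counts of 0 in RVM and for the interaction are reached by every split, so these splits do not test them. Of 100 splits drawn for the interaction the highest gave 929 genes, and the next 826 and 822. These 3 splits keep the thalamus groups whole and put RVM CFA 1 and 3 on the side opposite to the thalamus CFA libraries and to RVM CFA 2. The other splits gave at most 30. With RVM CFA 1 and 3 reversed, changes that both regions share add up in the interaction. The high counts thus go with shared changes and do not show a difference between the regions.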
